A study of Mus musculus with 8 samples.

How the data were processed

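RNA from bone marrow cells sorted by flow cytometry for the surface proteins CD71 and Ter119 was measured on Illumina bead arrays, which report gene expression as the fluorescence of probes carried on beads. The mice were 8 to 12 weeks old, and 100 ng of RNA per sample was amplified and labelled with biotin, per the labels. The 8 samples fall into 4 KAP1 knockout (KO) samples, coded A4, A8, A11 and A13, and 4 wild-type (WT) samples, coded C4, C6, C8 and C9, and the group of each was taken from its title. The labels do not state that each sample came from a separate animal, so the p-values measure the spread between these samples only, part of which may be technical.

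The deposited values are probe intensities on a linear scale for 45281 probes, processed by the authors with BeadStudio 3.1.3 per the submitters' processing notes. The settings of the background subtraction and of the normalization are not given in the sources used here. The values themselves show 2 steps. At 4959 of the 5000 highest ranks, all 8 arrays held the same intensity within 0.1 percent, as quantile normalization leaves them, and no value lay below 20. Between 73.1% and 73.2% of the probes sat at that floor on each array, so the median probe was at the floor on all arrays. Quantile normalization removes differences in overall brightness, and the floor hides changes below it. A fold change against a group with all 4 arrays at the floor is therefore a lower bound, written as "at least", with the floor intensity of 20 standing for each such array. A group with only some arrays at the floor gives an understated fold if their true signals lie below it. If an array lost signal at a probe, the fold is instead overstated. The number of arrays above the floor is stated for the leading genes.

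A second deposited table holds the authors' fold change and a p-value per probe. Its signed fold is the ratio of the geometric mean intensities of the groups for all 45281 probes (relative tolerance 0.0001). Its p-value column, headed as a detection p, equals an unequal-variance 2-sample test on the log2 values for all 18468 probes that have one. Another table, of signals before normalization, has 8 signal columns whose names match no sample label. These 8 columns were not used, since they could not be assigned to samples without relying on their order or values. The design fixed before the data were examined had assumed that table, with background correction from its detection p-values, and the test below uses the authors' normalized intensities in its place.

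Intensities were converted to log2. A probe was tested if it lay above the floor on at least 4 of the 8 arrays, whatever the group, which left 12259 probes. KO was compared with WT by lmFit and eBayes in limma 3.58.1 under R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Standard errors are those of the moderated fit, and group values are given as mean ± SD of log2 intensity over 4 samples. The array table names 1 gene for 34885 probes, several for 18 and none for 10378. Of these probes, 34807 were matched by Entrez identifier to the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only, and no symbol changed. No coordinates are given, because no genome build is stated for the array. Each of the 7178 tested genes is represented by its tested probe of the highest mean over the 8 arrays.

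Before the data were examined, 25 gene lists were fixed, covering mitophagy and autophagy, the erythroid programme, organelle and ribosomal genes, stress and cell cycle genes, KAP1-related genes and markers of other bone marrow cells. The 23 lists with at least 5 measured genes were tested with camera in limma, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera compares a list with all other genes. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction, were run as alternatives. The genes named were also chosen by a rule fixed beforehand. They are Trim28, the 12 largest rises and 12 largest falls among genes with an established symbol that passed the threshold without overlap between the groups, up to 4 genes per list with the smallest p among those past the threshold (the 2 with the smallest p where none passed), and a set of erythroid and mitophagy genes chosen whatever their result, of which Hbb-b1 had no tested probe under that name. Genes named outside the rule are said to be so.

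The fit was tested on simulated data built from the mean and the moderated spread of the 12259 probes. Noise was drawn independently for each probe and array, with no array that stood apart. At a true log2 change of 1, 15% of 100 changed probes were recovered. At a log2 change of 2, 86% of 100 were recovered, with 5 false calls in all. The number of arrays limits the precision, and most 2-fold changes were missed in this simulation with 4 arrays per group. Only 200 probes were changed in it, whereas 682 were called in the data. The adjusted threshold was therefore stricter in the simulation, and its recovered share need not carry over to the data. Its 5 false calls need not carry over either, since probes of real arrays can vary together. The alternatives tried were other thresholds, other probe filters, array weights, a mean-dependent robust prior, a block for the replicate number, the mean over the probes of a gene, and the omission of each sample in turn. Python 3.11.15 with matplotlib 3.10.9 drew the figures.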

Results

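The series measured gene expression in CD71+Ter119+ bone marrow cells of mice with and without KAP1. CD71 is the transferrin receptor and Ter119 a surface marker of the erythroid lineage, so the sort enriches for red cell precursors. KAP1, encoded by Trim28, is a corepressor that KRAB zinc finger proteins bring to DNA. The title of the series names mitophagy and microRNAs in red cell formation, and the single comparison is of 4 KO with 4 WT samples. Each array held between 12143 and 12199 probes above the floor of the values. All 8 samples expressed Xist, with intensities from 384 to 1642 at its 2 bright probes. The 5 probes of Eif2s3y, Kdm5d and Usp9y on the Y chromosome were at the floor in every sample, and the 1 tested probe of Uty, also on that chromosome, reached an intensity of at most 34.0.

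Trim28 was lower in every KO sample than in any WT sample. Its probe (ILMN_1227225) gave intensities of 207, 171, 141 and 131 in KO samples A4, A8, A11 and A13, and of 740, 395, 641 and 406 in WT samples C4, C6, C8 and C9. This is a 3.28-fold difference, from 9.04 ± 0.46 to 7.32 ± 0.30 in log2 intensity (log2 fold change -1.71, SE 0.27, adjusted p = 0.0085 in limma, n = 4 each). The position of the probe relative to the deleted part of the gene is not known here, so a remaining signal can come from transcripts that lack that part or from cells that kept the gene.

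KO cells differed from WT cells in both directions, with 301 probes higher and 381 lower, corresponding to 172 and 233 genes. By measured fold, which the floor understates for some genes, the largest named rise was in Stfa1, a stefin A-type inhibitor of cysteine proteases. It averaged 11.33 ± 1.07 in KO and 5.82 ± 1.40 in WT, a 45.8-fold difference with 3 of 4 WT samples above the floor. Its relatives Stfa2 (21.6-fold, 1 WT sample above the floor), Cstdc5 (11.4-fold, 1 WT sample barely above it) and Cstdc4 (8.27-fold) rose as well, and one probe of this cluster of closely related genes need not tell its members apart. Erfe, which encodes the erythroblast hormone erythroferrone, rose 11.1-fold with 2 WT samples above the floor. Cish, a cytokine-induced inhibitor of receptor signalling, rose 8.64-fold, from 5.72 ± 0.71 to 8.83 ± 0.52. Several genes were above the floor in KO samples and at it in all 4 WT samples. Cyp2a5, a cytochrome P450 with near-identical relatives, was at least 24.5-fold higher, and the stress-induced pseudokinase Trib3 and the platelet beta-tubulin Tubb1 were each at least 11.6-fold higher. Bounds for Nccrp1, the actin-severing protein gene Scin and the amino acid transporter gene Slc1a4 were at least 11.3-fold, 7.87-fold and 6.75-fold.

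By measured fold, the largest fall among named genes was in Hbq1a, which encodes theta globin, from 9.13 ± 0.42 to 5.39 ± 0.20, a 13.3-fold difference (adjusted p = 0.000131 in limma). Bcl2l1, which encodes the survival protein Bcl-xL, fell 10.4-fold with KO sample A8 at the floor, and Mff, a factor of mitochondrial fission, fell 7.47-fold. Dcaf12, the potassium channel gene Kcnc4, Reln (3 KO samples above the floor, A8 at it) and Erich2 fell between 7.71-fold and 11.5-fold. The ubiquitin ligase gene Mkrn1, Grap2 (3 KO samples above the floor, A8 at it), Ccndbp1 and Fezf2 fell between 6.31-fold and 7.34-fold. Cfap126, at the floor in all 4 KO samples, was at least 6.43-fold lower. Of these 24 genes with the largest changes, 22 stayed past the threshold whichever sample was left out. Cstdc4 lost its call without A4, A11, A13, C4 or C8 (adjusted p between 0.0514 and 0.0796), and Bcl2l1 without A11, A13, C4, C8 or C9 (between 0.0536 and 0.0922). Without A8 the log2 fold change of Bcl2l1 moved from -3.38 to -2.58, and its 2 other probes were lower by 3.33-fold and 2.58-fold without passing (6.25-fold and 4.53-fold without C8, which was at the floor for both). The other probe of Reln was at least 2.23-fold lower and did not pass (adjusted p = 0.108). The other probe of Ccndbp1 was 15.1-fold lower without passing (adjusted p = 0.0712), with A8 at the floor, and 6.03-fold lower without A8. Other probes of Mff (2.67-fold), Grap2 (4.96-fold) and Mkrn1 (7.83-fold and 3.11-fold) passed as lower too. A further 46 higher and 82 lower probes have no single gene name here. The strongest of them were ILMN_2476405 (log2 fold change 5.82) and ILMN_1244995 (5.40) among the higher, and ILMN_3059393 (-4.22) and ILMN_2527631 (-4.18) among the lower.

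The counts depended on individual samples. KO sample A8 stood apart, with a mean correlation of 0.894 with its own group against at least 0.934 for each other array, but 289 higher and 317 lower probes were called without it, and 476 of those 606 were among the 682 called with all samples. Leaving out any other sample moved at least 1 count by over 1.5 times: 182 higher and 219 lower without A4, 119 and 197 without A11, 99 and 162 without A13, 91 and 163 without C4, 557 and 586 without C6, 149 and 245 without C8, and 97 and 173 without C9.

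A minority of mitophagy and autophagy genes passed the threshold as lower in KO cells, and none as higher. Bnip3l, which encodes the mitochondrial receptor needed to clear mitochondria from maturing red cells, fell 4.13-fold, from 13.97 ± 0.24 to 11.93 ± 0.23 (log2 fold change -2.05, SE 0.20, adjusted p = 0.0013). The endophilin gene Sh3glb1 fell 3.1-fold, from 11.41 ± 0.41 to 9.78 ± 0.19. Ulk1, the kinase that starts autophagy, fell 2.97-fold, the autophagy receptor gene Sqstm1 2.68-fold, Atg12 2.15-fold and Gabarapl2 2.12-fold, the last with 2 KO samples above the floor. Of the 34 measured genes of the mitophagy and autophagy list, 7 fell (the seventh was the lysosomal protease gene Ctsb, named outside the rule, by 1.74-fold), none rose and 27 did not pass. Adjusted over the list alone, 8 fell, and at an unadjusted p under 0.05 there were 2 higher and 8 lower. The list as a whole had a median log2 fold change of -0.15, with 11 of 34 genes above 0, and its mean per sample lay between 7.14 and 7.24 in KO and between 7.41 and 7.66 in WT. It was lower than other genes by camera (adjusted p = 0.0018), a call lost with an estimated correlation (adjusted p = 0.296 with an estimated correlation). In the same samples, the mean of B-cell markers was 7.10 ± 0.53 in KO and 8.26 ± 0.60 in WT. A list of late erythroid genes, added later, had a median log2 fold change of -0.77. These falls therefore cannot be told apart from an earlier erythroid stage of the KO cells. Bnip3l and Sh3glb1 kept their calls in all 8 fits that left out 1 sample. Atg12 lost it without A13 (adjusted p = 0.0510), Sqstm1 without A11, A13, C4 or C9 (up to 0.0633), Ulk1 without any sample but A8 or C6 (up to 0.108) and Gabarapl2 without any but C6 (up to 0.124).

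**Figure D1:**
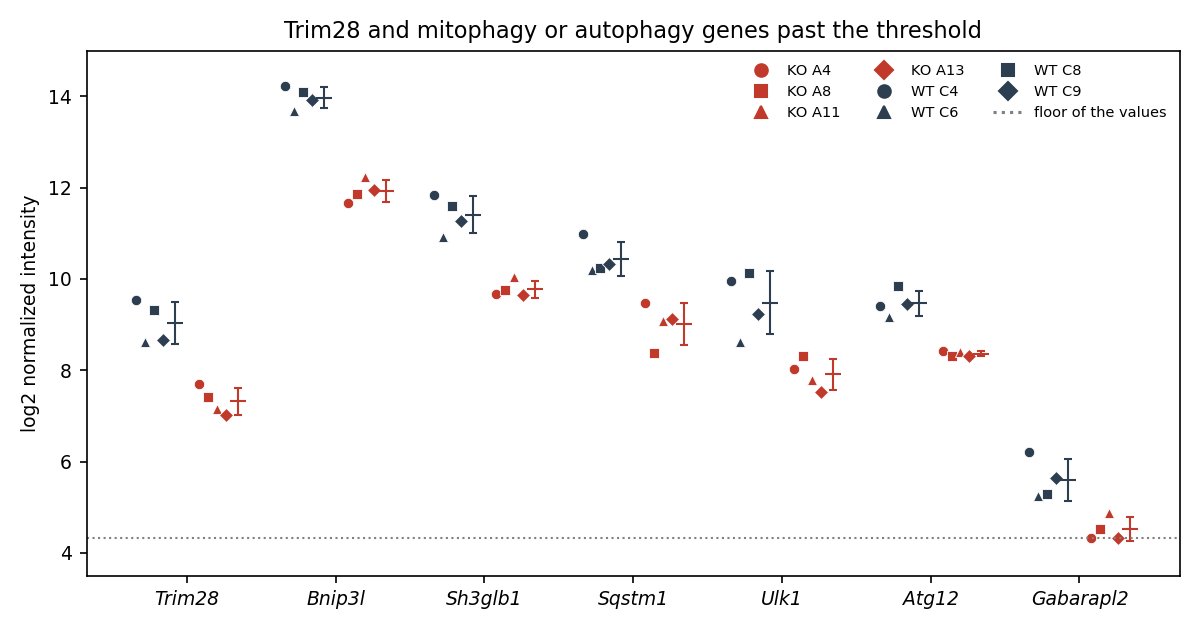
Log2 normalized intensity of Trim28 and 6 mitophagy or autophagy genes in each of the 8 samples (WT left in dark blue, KO right in red, one symbol per sample), with bars for mean ± SD and a dotted line at the floor. For every gene shown, the 4 KO samples lie below the 4 WT samples, and Bnip3l averages 13.97 in WT and 11.93 in KO.

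Erythroid genes moved unevenly. Of the 33 measured genes of the erythroid maturation list, 5 fell, none rose and 28 did not pass, and 7 fell when adjusted over the list alone. Besides Bcl2l1, these were the nuclear transport gene Xpo7 (5.84-fold), Alas2 (2.07-fold), which encodes the erythroid enzyme of the first step of heme synthesis, Trim10 (1.74-fold) and, outside the naming rule, the globin gene Hbb-b2 (4.15-fold). Other hallmark genes did not pass the threshold. Tfrc, which encodes the CD71 used for sorting, averaged 12.93 ± 0.61 in KO and 12.77 ± 0.86 in WT (adjusted p = 0.841). The lineage factor gene Klf1 averaged 11.65 ± 0.07 and 11.33 ± 0.13 (adjusted p = 0.255), and Hba-a1 14.45 ± 0.25 and 14.71 ± 0.05 (adjusted p = 0.398). Hba-a1 lay near the highest intensity of every array (36264.5), where differences can be compressed. The globin gene Hbb-bt, named outside the rule, was lower in every KO sample at ILMN_1235372 (5396 to 7330, WT 10430 to 14380) and ILMN_1236718 (12795 to 18043, WT 22314 to 25180). Its brighter probes overlapped between the groups. Gata1 averaged 7.98 ± 0.51 and 7.87 ± 0.18 (adjusted p = 0.811), and its other probe differed in direction (log2 fold change -0.83). The list had a median of -0.16 and passed camera (adjusted p = 0.0031), but not with an estimated correlation (adjusted p = 0.450 with an estimated correlation) and not by fry (adjusted p = 0.088). Its median was -0.29 without C6, -0.25 without C9 and -0.091 without C8. Among 28 heme and iron genes, the iron-sulfur scaffold gene Iscu (3.94-fold) and the mitochondrial carrier gene Slc25a39 (4.03-fold) fell and Tmem14c (1.92-fold) rose, with no shift of the list (adjusted p = 0.716). Xpo7, Iscu and Slc25a39 kept their calls whichever sample was left out. The other probe of Xpo7 was 2.37-fold lower and did not pass (adjusted p = 0.414), with C8 and A8 at the floor, and 4.58-fold lower without C8. The other probe of Trim10 was 4.53-fold lower without passing (adjusted p = 0.301), but 1.61-fold lower without A8 and 6.81-fold lower without A4. Of the 2 other probes of Tmem14c, 1 passed (1.89-fold higher). Alas2 lost it without A13 (adjusted p = 0.0521), Trim10 without any sample but A4 or C6 (up to 0.112) and Tmem14c without A4, A11, A13, C4 or C9 (up to 0.0771).

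Genes for ribosomes and for the respiratory chain were higher in KO cells as groups, by small amounts each. Of 68 mitochondrial ribosome genes, 66 had a fold change above 0, with a median log2 fold change of 0.45 (camera adjusted p = 7.81e-08, and adjusted p = 0.363 with an estimated correlation). Their mean per sample lay between 7.87 and 8.10 in KO and between 7.34 and 7.75 in WT. Only 3 passed singly, Mrpl11 (2.96-fold, 1 WT sample above the floor), Mrpl22 and Mrpl18, and 14 passed when adjusted over the list alone. Of 50 cytosolic ribosome genes, 44 had a fold change above 0, with a median of 0.41 (camera adjusted p = 6.44e-06, and adjusted p = 0.296 with an estimated correlation). Rps2 (2.05-fold), Rplp1, Rpl10a and Rpl38 passed, and 13 passed over the list alone. The other probe of Rps2 was 1.14-fold higher and did not pass (adjusted p = 0.811), but was 1.59-fold higher without A8, with no overlap between the groups. Of 69 respiratory chain genes, 55 had a fold change above 0, with a median of 0.36 (camera adjusted p = 0.000235, and adjusted p = 0.427 with an estimated correlation). Atp5e, a subunit of ATP synthase, was the single one to pass (1.93-fold, 2 WT samples above the floor), and none passed over the list alone. The median over all tested probes was 0.09. Markers of other cells differed between the same samples, with means in KO and WT of 7.10 and 8.26 for B-cell and 6.0 and 5.16 for megakaryocyte and platelet genes. WT sample C4 had the lowest mitochondrial ribosome mean and the highest B-cell mean (9.07). WT sample C6, with the next highest B-cell mean (8.26), went the other way, with the highest mitochondrial ribosome mean in WT (7.75). Of the genes named, Mrpl11 alone kept its call in all 8 fits with a sample left out. Rps2 lost it without A13 (adjusted p = 0.0517), Rplp1 without A4, A11, A13, C4 or C9 (up to 0.0792) and Rpl10a without any sample but C6 (up to 0.123). Mrpl18 lost it without any but A8 or C6 (up to 0.109), Atp5e without any but A4 or C8 (up to 0.112), and Mrpl22 and Rpl38 without any one of the 8 (up to 0.122 and 0.125).

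**Figure D2:**
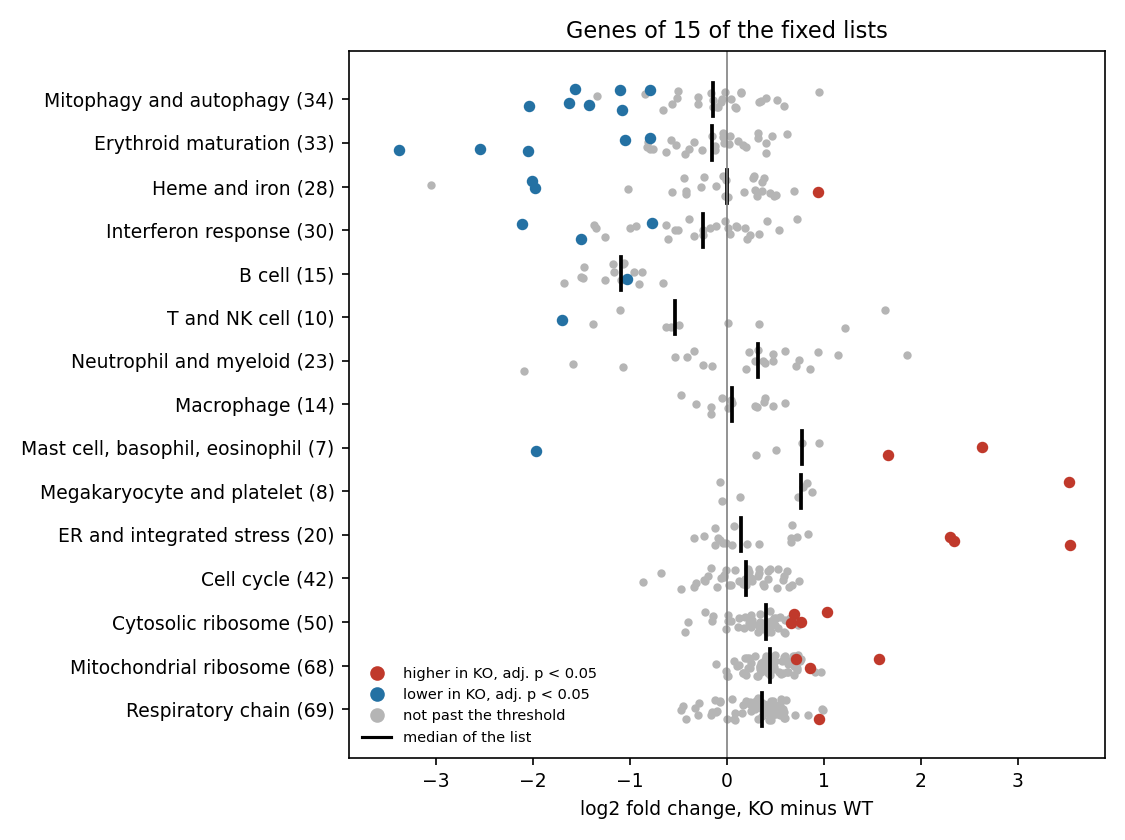
Log2 fold change (KO minus WT, horizontal axis) of every measured gene in 15 of the gene lists, with the number of genes in brackets, a black bar at the list median, and colour for genes past the threshold. The B-cell list lies wholly below 0 with a median of -1.10, and 66 of the 68 mitochondrial ribosome genes lie above 0.

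Stress genes changed in a small group. Of 20 genes of the endoplasmic reticulum and integrated stress list, 3 rose, none fell and 17 did not pass, and 6 rose when adjusted over the list alone. These were Trib3, Chac1, which degrades glutathione (at least 5.09-fold), and the mitochondrial serine enzyme gene Shmt2 (4.94-fold, 2 WT samples above the floor), and all 3 kept their calls whichever sample was left out. The other probe of Shmt2 was 1.64-fold higher, with overlap between the groups, and did not pass (adjusted p = 0.421). It was 2.32-fold higher, with no overlap, without A8. The list passed camera (median 0.14, adjusted p = 0.0267, and adjusted p = 0.296 with an estimated correlation), but not without A4 (0.0580) or without C6 (0.0592). Its median was 0.28 without A11, 0.29 without A8 and 0.30 without C6. Among 20 antioxidant genes, Cat, which encodes catalase, fell 4.94-fold and Gclm 1.76-fold. Interferon-response genes were lower as a list, with a median of -0.25 (camera adjusted p = 0.0031, and adjusted p = 0.450 with an estimated correlation), but did not pass fry (adjusted p = 0.121). WT sample C4 had the highest mean of both this list (8.32) and the B-cell markers (9.07), and the interferon median was -0.15 without C4 and -0.38 without C9. Of its 30 genes, Rsad2 (2.85-fold), Oasl2 (4.33-fold) and Ifi27 (1.71-fold) fell, none rose, and 4 fell over the list alone. Cat and Rsad2 kept their calls in all 8 fits with a sample left out. Oasl2 lost it without A13 (adjusted p = 0.0553), and Gclm and Ifi27 without any sample but A8 or C6 (up to 0.111 and 0.121).

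Markers of other bone marrow cells differed between the groups by cell type. All 15 measured B-cell genes had a fold change below 0, with a median of -1.10 (camera adjusted p = 1.72e-07, and adjusted p = 0.363 with an estimated correlation), and fry did not pass (adjusted p = 0.0588). H2-Aa alone passed over all probes (2.04-fold lower), and 12 passed when adjusted over the list alone. H2-Aa lost its call without any sample but A13 or C8 (adjusted p up to 0.112). Per sample, the B-cell mean ranged from 6.42 to 7.66 in KO and from 7.62 to 9.07 in WT, so the groups overlapped slightly. Of 7 mast cell, basophil and eosinophil genes, Cpa3 (6.18-fold, 1 WT sample above the floor) and Fcer1a (3.16-fold) rose and Prss34 fell 3.91-fold, and the list did not shift by camera (adjusted p = 0.17), though it did without C4 (0.0452). Fcer1a lost its call without A13 (adjusted p = 0.0512) and Prss34 without A13, C4 or C9 (up to 0.0882). Of 8 megakaryocyte and platelet genes, Tubb1 rose and 7 did not pass. The list passed camera narrowly (median 0.76, adjusted p = 0.0487, and adjusted p = 0.296 with an estimated correlation), but not without C6 (0.175). Its mean was 6.0 ± 0.09 in KO and 5.16 ± 0.10 in WT. Of 10 T and NK cell genes, Cd2 fell 3.26-fold and the list did not pass (adjusted p = 0.0750), though it did without A4, C8 or C9 (down to 0.0167). None of the 23 neutrophil and myeloid, 14 macrophage or 8 stem and progenitor genes passed in limma (none over the lists alone either), with list medians of 0.32, 0.05 and 0.08, by the probe that represents each gene. Gata2, a stem and progenitor gene, averaged 2.36-fold higher in KO (adjusted p = 0.105) and passed without A13 (0.0216), and Kit averaged 3.48-fold higher (log2 fold change 1.8, adjusted p = 0.111, and 1.20 without A8). A second probe of the myeloid gene Ms4a3 did pass (2.18-fold higher, 1 WT sample above the floor, adjusted p = 0.0208), where its representing probe, also higher, did not (adjusted p = 0.160). At an unadjusted p under 0.05 there were 1 higher and 2 lower neutrophil and myeloid genes, 0 macrophage genes and 2 higher stem and progenitor genes. Among them, S100a9 averaged 12.75 ± 0.66 in KO and 13.82 ± 0.28 in WT (adjusted p = 0.0882), so neutrophil transcripts were abundant in the sorted samples of both groups.

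**Figure D3:**
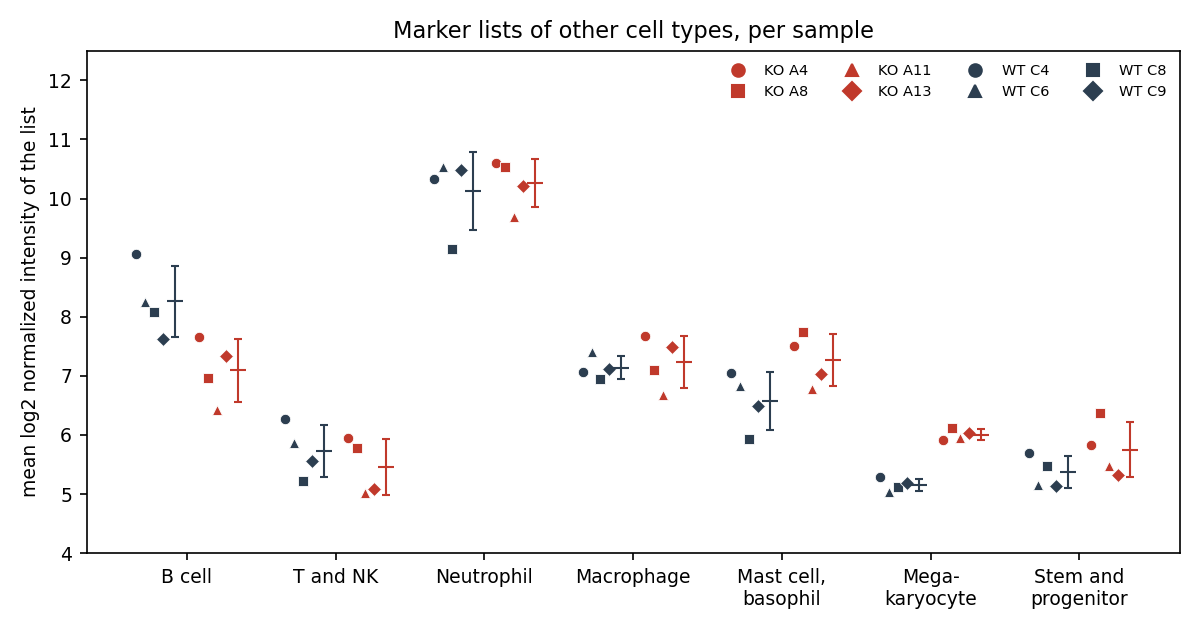
Mean log2 normalized intensity of the measured genes of 7 marker lists of other cell types in each of the 8 samples (WT left in dark blue, KO right in red, one symbol per sample), with bars for mean ± SD. B-cell markers average 7.10 in KO and 8.26 in WT, and megakaryocyte and platelet markers 6.0 and 5.16.

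The remaining lists did not pass camera. In the list of KAP1 partners and heterochromatin genes, Trim28 was the only one of 18 genes to pass over all probes. Adjusted over the list alone, 3 more passed, all higher (Setdb1 by 2.68-fold, Mbd1 by 2.59-fold and Hdac2 by 1.48-fold, named outside the rule). Of 11 microRNA biogenesis genes 1 passed, Tarbp2 (1.84-fold higher, with 1 WT sample above the floor). Of 98 zinc finger genes of the Zfp series, Zfp276 rose 2.36-fold (2 WT samples above the floor; its other probe 1.29-fold, adjusted p = 0.369) and Zfp874b fell 2.41-fold. Of 9 imprinted genes, Snurf was at least 2.03-fold lower. Of 18 p53 and apoptosis genes, Tnfrsf10b fell 2.51-fold, while adjusted over the list alone 3 were higher and 2 lower, and at an unadjusted p under 0.05 there were 6 higher and 2 lower. Of 14 immediate early and heat shock genes, Ier3 rose 3.72-fold. Of 42 cell cycle genes none passed in limma, over all probes or over the list alone, while 7 were higher at an unadjusted p under 0.05. The lowest adjusted p was 0.0620 for Mcm5, which passed without C6 (0.0304), and the list passed camera without A8 or C8 (adjusted p down to 0.0229). Of the genes just named, Zfp276 kept its call whichever sample was left out. Ier3 lost it without A4, A11 or C4 (adjusted p up to 0.0581) and Zfp874b without A4, A11, A13, C4 or C9 (up to 0.0600). Tarbp2 lost it without any sample but A4 or C6 (up to 0.0936), Tnfrsf10b without any but A8 or C6 (up to 0.112) and Snurf without any but C6 (up to 0.122). Adjusted p-values of the 14 lists that did not pass ran from 0.0750 to 0.966, and for 6 of them, the antioxidant, heme and iron, imprinted, macrophage, microRNA and Zfp lists, the median, mean and test direction differed in sign. The germline list, with 4 measured genes, and the sex-linked list, with 2, were too small to test. Rec8, a meiotic cohesin gene named outside the rule, was at least 2.38-fold higher, with all 4 WT samples at the floor (adjusted p = 0.0040).

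Of the tested probes, 2184 (17.8%) had no overlap between the groups, where 2.86% are expected on average over random divisions of the samples. An unadjusted p under 0.05 in limma was found for 3066. Probes of the same arrays can vary together, so a single chance division can give a share far from 2.86%. The excess therefore cannot exclude such a division. In the authors' deposited table, the log2 fold changes of the tested probes equal those computed here (Pearson r = 1 across probes, which are not independent replicates). Adjusting the p-values of the authors' deposited table over the same probes gave 94 higher and 114 lower.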

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

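The tests of both B-cell explanations were chosen after the B-cell result was seen, and the others in this part before their results. Among 165 groups of 4 samples checked for a sample far from the other 3, 18 had one, and chance gives about 1 in 20, or 8.25. In 6 of the 18 the other 3 samples were tied at the floor, so any value above it stood apart and these 6 say nothing about chance. Of the remaining 159 groups, 12 had one, against 7.95 by chance.

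KO sample A8 accounted for 5 of these. Its mean correlation with its own group was 0.894, its deviations from the group mean had an SD of 0.71 against 0.34 to 0.39 in the other KO samples, and its log2 intensities of Cstdc4 (12.01, high), Kcnc4 (6.46, low) and Bcl2l1 (4.32, the floor) lay apart. In A8, 441 probes lay over 2 log2 units below all other KO samples, against at most 66 by the same rule in any other array, and 8 lay as far above. A change of whole genes would lower the other probes of the same genes, and these deviated by a median of -0.062 (bootstrap interval -0.16 to 0.05, 202 genes). Other probes that were themselves over 2 log2 units low were left out of this median. It therefore cannot decide against a change of whole genes, and shows only that the remaining probes of these genes did not follow. Genes whose probes disagreed by over 2 log2 units numbered 301 in A8 and 73 in the next array, 4.12 times as many, so a loss of signal at single probes is a candidate explanation, and whether it arose in the sample, the labelling or the array stays open. No biological explanation was tested, since A8 shares its labels with the other KO samples.

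The B-cell list was lower in KO samples by camera, though the sort for Ter119 should leave out B cells. It did not pass camera with an estimated correlation (adjusted p = 0.363) or fry (adjusted p = 0.0588). Lower purity of the WT samples for all other cell types would lower neutrophil markers in KO as well, but their median was 0.32 (bootstrap interval over genes -0.25 to 0.48). It ran from -0.011 to 0.67 with 1 sample left out. Resampling genes does not measure the spread between samples, whose neutrophil means ran from 9.69 to 10.60 in KO and from 9.15 to 10.54 in WT. These neutrophil markers gave no sign of such a fall, but 4 samples per group cannot exclude it. Abundant markers of this kind, named after their values were seen, differed in direction without passing the threshold. In KO and WT, S100a8 averaged 14.01 ± 0.38 and 14.55 ± 0.16, S100a9 12.75 ± 0.66 and 13.82 ± 0.28, and Ltf 14.02 ± 0.66 and 13.16 ± 0.61. Lower MHC class II expression in other cells would spare the other B-cell genes, but the 11 genes outside that class had a median of -1.17, all below 0. The interval of -1.48 to -1.07 is over genes and leaves out the spread between samples. Of the 15 genes, 4 belong to MHC class II antigen presentation, which other cells express too, and none is in another list. The most abundant of those 4, Cd74, averaged 10.84 ± 0.56 in KO and 11.75 ± 0.27 in WT. A smaller share of B-lineage cells in KO marrow or in the KO sort stays open and was not tested.

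The rise of ribosomal, mitochondrial ribosomal and respiratory chain genes was weighed against rank shifts forced by quantile normalization. The median of the mitochondrial ribosome list lay at percentile 100 of 10000 random lists matched on mean level, whose central range ended at 0.22. Random sets of genes of like mean level therefore did not rise as much. That list had already passed camera against all other genes, which the percentile partly repeats, so it cannot decide against such shifts. Random lists hold unrelated genes, so the percentile does not weigh a joint drift of co-expressed genes. With an estimated correlation the list did not pass camera (adjusted p = 0.363). An earlier average erythroid stage of the KO cells is a candidate explanation. It predicted that late erythroid genes not examined before would be lower, and their median was -0.77, with nucleolar genes higher at 0.64. Both lists were written after the fixed lists had been seen and were measured in the same samples. Their shifts are therefore not independent of the pattern they were set against. The late list passed camera (adjusted p = 4.24e-09) but not with an estimated correlation (adjusted p = 0.135 with an estimated correlation), and an effect of KAP1 loss on these genes at an unaltered stage cannot be excluded by these values.

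The other samples far from their group are given as values in log2 intensity. In WT samples, with the other 3 at the floor, Stfa2 was at 5.39 and Cstdc5 at 4.32 in C9, Gata2 at 4.35 in C9, and Cpa3 at 5.69, Tarbp2 at 4.56 and Mrpl11 at 4.38 in C6. In C4, Sqstm1 (10.98), Kit (5.37) and Cd2 (7.69) were high. In C8, Gata1 was high (8.13) and the mean of the neutrophil and myeloid list low (9.15), in C6 Hba-a1 was low (14.63), and in KO sample A11 Mkrn1 was high (9.56).

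Among the 35 splits of the 8 samples into 4 and 4, only the real split had as many as 682 probes past the threshold. The highest other split gave 20. The smallest share this test can give is 1 in 35, so it cannot exclude a chance division of the samples. The other splits mix KO with WT samples, so any difference between KO and WT widens the spread within each mixed set and can lower its count.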

How the results depend on the processing

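The filter on all 8 arrays, the adjusted p-values of the authors' deposited table, the 2-level block and, for single genes, the mean over probes and the other probes without each sample were chosen after seeing the data. The fall of Trim28 and of the mitophagy list kept direction and call in limma under array weights, a trended robust prior, both other probe filters, the mean over probes and each omission of a sample, with Trim28 between -1.85 and -1.55 and the list between -0.21 and -0.12 on omission. The list median was -0.29 with both the filter on all 8 arrays and the replicate block. The list kept its median (-0.15) but lost its call with an estimated correlation (adjusted p = 0.296), where adjusted p ran from 0.000293 to 0.012 under the other settings.

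Counts higher and lower in KO (301 and 381) became 755 and 670 at an adjusted p of 0.10, 836 and 702 with array weights, and 94 and 114 from the p-values of the authors' deposited table. Probes above the floor on all 8 arrays gave 171 higher. With 1 sample left out they ranged from 91 to 557 higher and from 162 to 586 lower. The trended robust prior (425 and 424), no filter (424 and 366) and a log2 change above 1 (219 and 322) moved them less. Fewer probes bear on the filter count. The rise to 557 and 586 without C6 is not a matter of fewer samples, and the cause of it and of the other shifts was not tested. Of 62 named genes past the threshold besides Trim28, 35 stayed past it in all 8 omissions, 27 lost it in 1 or more, and none changed sign. As a mean over probes, 5 lost it: Bcl2l1 (-2.16, adjusted p = 0.0642), Rpl38 (0.66, 0.0512), Rps2 (0.61, 0.179), Tmem14c (0.73, 0.0596) and Trim10 (-1.49, 0.174). For all but Rpl38, A8 was the lowest KO sample at an added probe. Of the 9 lists past camera, 7 kept the call in all 8 omissions. Array weights, no filter and the filter on all 8 arrays each ended the call of 1 list. Among named genes, 7 lost their calls with no filter, 2 with the trended robust prior and 1 with array weights.

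The sample codes share the numbers 4 and 8 between the groups. Deviations from the group mean correlated at 0.26 for A4 with C4 and 0.22 for A8 with C8. Pairs with unequal numbers ran from -0.30 (A4 with C8) to 0.31 (A13 with C9). Between these lay A8 with C4 at 0.10 and A11 with C9 at 0.25. Equal numbers therefore did not stand apart, and 2 pairs do not show that numbers pair the samples. A fit with the number as a replicate block left 1 residual degree of freedom and called 0 higher and 0 lower probes in limma (945 and 991 at an unadjusted p under 0.05), with Trim28 at -1.87 (adjusted p = 0.259, against 0.0021 to 0.0356 elsewhere). A block of only codes 4 and 8 against the rest called 324 and 401, and 621 of those 725 were among the 682. With this block, 2 named genes and 1 list lost their calls.

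Direction changed only for results that never passed. Gata1 was -0.076 with array weights and -0.36 as a mean over probes, stem and progenitor genes -0.061 with array weights, imprinted genes -0.10 with no filter, microRNA genes -0.14 with the filter on all 8 arrays and -0.12 with the replicate block, and Zfp genes 0.016 with that block. With 1 sample left out, Gata1 ranged from -0.11 to 0.28, Tfrc from -0.10 to 0.53, heme and iron genes from -0.066 to 0.12, macrophage from -0.14 to 0.36, microRNA from -0.11 to 0.16, neutrophil from -0.011 to 0.67, stem and progenitor from -0.035 to 0.17 and Zfp genes from -0.061 to 0.027, and the cause was not tested.

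Not run, for want of sample names on the signals before normalization, were no background correction, an offset of 50 and a detection p of 0.01. Median scaling was void, since the median probe is at the floor, and no slide is given. The floor limits what is seen of dim genes, with 26813 probes at it on all arrays.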

Other observations

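The lists in this part were written after the fixed lists had been seen and before their own values were, and the genes named were chosen after their values were seen. Late erythroid genes were lower in KO cells. Of 28 measured genes of an added list, 8 fell, none rose and 20 did not pass, with 25 of 28 below 0 and a median of -0.77 (camera adjusted p = 4.24e-09, and adjusted p = 0.135 with an estimated correlation). Isca1, which takes part in iron-sulfur cluster assembly, fell 3.04-fold, from 13.57 ± 0.25 to 11.96 ± 0.08 (adjusted p = 0.0023). The kinase gene Riok3 fell 2.54-fold, the F-box gene Fbxo9 2.53-fold and Tent5c 2.44-fold. Of 19 nucleolar genes, 18 had a fold change above 0, with a median of 0.64 (camera adjusted p = 7.00e-05, and adjusted p = 0.184 with an estimated correlation). Nme1 (2.46-fold) and Bop1 (2.09-fold, 3 WT samples above the floor), the latter a factor of ribosome assembly, rose and 17 did not pass. B-cell markers (mean 7.10 in KO and 8.26 in WT) and megakaryocyte and platelet markers (6.0 and 5.16) differed between the same samples.

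Cish and Erfe, which rose 8.64-fold and 11.1-fold, are known as targets of erythropoietin signalling through Stat5, and the hypothesis that other targets rose with them was tested on an added list. Its 10 measured genes had a median of 0.45, with 7 above 0 and none past the threshold in limma (4 higher and 1 lower at an unadjusted p under 0.05). Over the list, fry in limma gave an adjusted p = 0.109, which leaves open whether these targets moved together. Osm averaged 6.20 ± 0.93 in KO and 4.92 ± 0.72 in WT (adjusted p = 0.156), and Pim1 5.58 ± 0.97 and 4.59 ± 0.50 (adjusted p = 0.223).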
